A study of Mus musculus with 12 samples.

How the data were processed

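Total RNA was extracted from micro-dissected neural tubes and 100 ng per sample was labelled with biotin and hybridised to Affymetrix mouse genome arrays, per the labels' protocols. The labels give 3 stages with 4 biological replicates each. The study also profiled microRNA, which is outside these 12 arrays. The submitters' processing notes name Affymetrix Expression Console 1.2.1, RMA and GCRMA, with no role or order, so which of these made which column is not given in the sources used here.

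The log2 values of 10 arrays were normalized across arrays before they were deposited, since their sorted values differed by at most 0.27 from each other. The values deposited for GD8.5 replicates 1 and 2 were intensities on a linear scale, with maxima of 88927 and 87593. The log2 arrays of GD8.5 had a slope of 1.01 on log2 of these intensities and a mean offset of 4.13 over probe sets above 5, so the base of the log scale was taken as 2. The SD of the difference was 0.26 for probe sets above 5, 0.70 from 2 to 5 and 1.37 below 2. The offset was 3.53 at the 25th percentile, 4.77 at the 50th, 4.47 at the 75th and 3.63 at the maximum, so no constant puts these 2 arrays on the scale of the others. The 2 linear arrays also differed more from each other than replicates 3 and 4 did, with an SD of 2.05 against 0.19 below 2. Whether another summary method or noisier low signals made the difference is not given in the sources used here. The plan fixed before the data were examined had all 12 arrays in 1 fit. The 10 log2 arrays were used instead, a choice made after the scales had been seen, and a fit of all 12 after log2 and quantile normalization was added as an alternative.

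The array held 45101 probe sets, of which 64 Affymetrix control sets were left out of the tests. Gene names came from the platform annotation, checked against a table of the mouse reference annotation that was used for names only. Of the probe sets, 34958 named 1 gene, 932 named several and 9160 had no gene in the table. Each gene was represented by its brightest probe set with 1 gene, which gave 18193 genes, 204 of them absent from the reference table. Among the genes that the rule below names, probe sets of Tgfb2, Mcm3, Epha7, Fzd3 and Smad2 were called in opposite directions in at least 1 comparison, and no result for these genes is given in the stage comparisons. The level of 39 olfactory receptor genes served as a background (95th percentile 1.42), a measure chosen after the data were seen.

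The values were fitted with limma 3.58.1 in R 4.3.3 with a mean per stage, which left 7 residual degrees of freedom and a prior of 3.86. Contrasts were GD9.0 minus GD8.5, GD9.5 minus GD9.0, GD9.5 minus GD8.5, and the second interval minus the first. Moderated tests were adjusted with the Benjamini-Hochberg method over genes, and a gene was called at an adjusted p under 0.05. Errors beside log2 changes are standard errors of this fit. The median log2 change over all genes was between -0.016 and 0.003 in the 4 contrasts. A total of 38 gene lists fixed before the data were examined, with at least 5 members measured, 1102 of 1171 members in all, was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether a list moves on balance 1 way and does not compare it with other genes. The lists cover neural, patterning, signalling, metabolic and cell cycle genes and markers of other tissues a dissection could carry over, and some genes are in more than 1 list. In 4, 2, 3 and 2 lists, by contrast, the sign of the median differed from the direction of camera, and in 4, 0, 3 and 1 that of the mean did, and no called list was among them.

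Genes were named by a rule fixed before the data were examined. It took the 6 largest rises and 6 largest falls among called genes whose arrays of both stages do not overlap, up to 2 rises and 2 falls per list described, 4 differences per direction between the intervals, and 6 constitutive genes with the highest mean. The rule assumed 4 arrays per stage and was applied to the 2 at GD8.5. Nothing in the labels says that equal replicate numbers share an animal or litter, so no block was used. The labels call the replicates biological without saying whether they are litters or pools. Sex was not given in the labels.

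The fit was tested on simulated data over 18193 genes with 200 changed genes. At a true 1.2-fold change it recovered 10%, 24% and 12% of genes for GD9.0 against GD8.5, GD9.5 against GD9.0 and GD9.5 against GD8.5. At a true 1.5-fold change it recovered 70% of genes for GD9.0 against GD8.5, 88% for GD9.5 against GD9.0 and 64% for GD9.5 against GD8.5, and at 2-fold 96%, 98% and 96%. There were 8, 10 and 8 false calls. Alternatives tried were median centring, repeated quantile normalization, the brighter probe sets, the mean of a gene's probe sets, leaving out probe sets shared between transcripts, an intensity trend with robust spread, array weights, a replicate block, a 2-fold threshold, narrower and wider limits for constitutive genes, fits of 2 stages, the 12 arrays, tissue levels as covariates, stage means raised to the background for list medians, and leaving out each of the 10 arrays. Leaving out a GD8.5 array leaves that stage with 1 array, which is assumed to vary like the other stages.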

Results

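Messenger RNA levels were measured in neural tubes, the embryonic precursor of the brain and spinal cord, dissected from ICR (CD-1) mouse embryos at 3 stages of gestation, named GD8.5, GD9.0 and GD9.5 for the day. ICR is an outbred stock. The stated aim was to find mRNAs with a constant level and mRNAs with a changing level over these stages. The series held 12 arrays, 4 labelled biological replicates per stage. The deposited values of 10 arrays were on a log2 scale, with medians from 1.75 to 1.82, and those of GD8.5 replicates 1 and 2 were linear intensities with medians of 92.2 and 98.3. Across probe sets, which are not independent replicates, Spearman correlations between these 2 arrays and the other GD8.5 arrays were 0.863 to 0.906, against 0.874 between the 2 linear arrays and 0.968 between replicates 3 and 4. Below a level of 2 the SD of the log2 difference was 2.05 between the 2 linear arrays and 0.19 between replicates 3 and 4, and at 5 and above it was 0.19 and 0.09, with 0.27 to 0.29 between the 2 kinds of array. The offset between the kinds was 3.53 at the lower quartile and 4.77 at the median. The stage comparisons therefore used the 10 log2 arrays, with n = 2 at GD8.5, n = 4 at GD9.0 and n = 4 at GD9.5, and this number of arrays limits their precision. The median SD of a gene between arrays of 1 stage was 0.07 at GD8.5, 0.10 at GD9.0 and 0.10 at GD9.5 on the log2 scale. The first principal component held 62.7% of the variance and placed the arrays in stage order. Of 18193 genes, 13018 had a mean level above 1.42, the level under which 95% of 39 olfactory receptor genes lay. Where a stage mean of a named gene lay at or under 1.42, the change between 2 stages is given as a bound against that level, and no detection calls were used.

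Markers of other tissues and signs of RNA quality differed between stages. The mean log2 level of the cardiac muscle list was 4.34 ± 0.09 (SD, n = 2) at GD8.5, 2.40 ± 0.04 (n = 4) at GD9.0 and 1.42 ± 0.04 (n = 4) at GD9.5. The endoderm and yolk sac list went from 4.96 ± 0.03 to 2.91 ± 0.02 and 1.94 ± 0.01. The erythroid list, of primitive red cell genes, went the other way, from 3.15 ± 0.02 to 3.67 ± 0.03 and 4.06 ± 0.02. The array's 18S ribosomal RNA control probe sets averaged 9.82 ± 0.01 (SD, n = 2), 8.81 ± 0.18 (n = 4) and 10.3 ± 0.09 (n = 4). The 3' minus 5' difference of the actin control probe sets, a sign of RNA length, was 0.71 ± 0.02, 0.56 ± 0.03 and 0.93 ± 0.03, and that of the Gapdh control probe sets moved less, at 0.039 ± 0.007, -0.00095 ± 0.013 and 0.049 ± 0.028. These 3 measures were higher at GD9.5 than at GD9.0 (two-sided exact permutation test, p = 0.0286 each, the smallest that 4 against 4 arrays can give). Sex-linked genes also differed between these stages. Xist, the X-inactivation transcript of female cells, stood at 8.87, 8.61 and 9.16 at the 3 stages and rose from GD9.0 to GD9.5 by 0.54 ± 0.05 (SE, 3 of 3 probe sets), while the Y-linked genes Uty (-0.58 ± 0.07, 2 of 4 probe sets) and Eif2s3y (-0.43 ± 0.06, 1 of 2 probe sets) fell and Kdm5d, also Y-linked, was at -0.19 ± 0.12. The Eif2s3y call was lost with 12 arrays after log2 and quantile normalization (-0.46). The list of 5 sex chromosome genes was not called by limma's camera with Benjamini-Hochberg adjustment (adjusted p = 0.298). Of its genes 1 was higher and 2 lower, the same adjusted over the list alone. It joins Xist with Y-linked genes, so a test for 1 direction can miss opposite moves and does not weigh against them. A mixed form of fry, which counts moves either way, gave it a Benjamini-Hochberg adjusted p of 0.00017, but called 36 of the 38 lists.

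**Figure D1:**
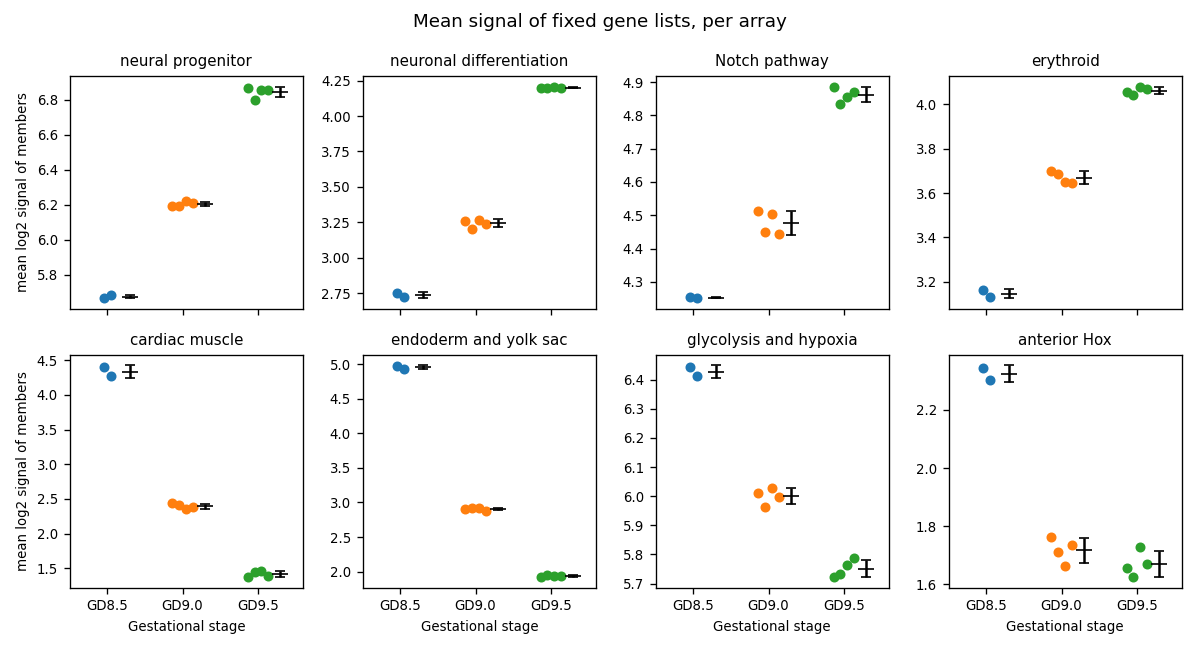
Mean log2 level of the members of 8 gene lists in each of the 10 log2 arrays, by stage, with points for arrays and error bars for the stage mean and SD. Cardiac muscle and endoderm and yolk sac levels were highest at GD8.5 (4.34 and 4.96) and lowest at GD9.5 (1.42 and 1.94), and neural progenitor and neuronal differentiation levels were highest at GD9.5 (6.84 and 4.20).

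From GD8.5 to GD9.0, 18 of 31 neural progenitor genes rose, and 19 of 22 cardiac muscle genes and 25 of 28 endoderm and yolk sac genes fell. Rspo2, a secreted activator of Wnt signalling, was 6.86-fold higher at GD9.0 (log2 change 2.78 ± 0.11 SE, n = 4 against 2), and Neurod1, a basic helix-loop-helix factor of neuronal differentiation, was at least 6.10-fold higher, from a level of 1.40 at GD8.5. Prl8a2, a prolactin family hormone of the decidua, was 30.8-fold lower (-4.95 ± 0.10), and Apoa1, the main protein of high-density lipoprotein made in yolk sac and liver, was 16.2-fold lower (-4.01 ± 0.10 SE). By limma with Benjamini-Hochberg adjustment these 4 genes had adjusted p from 4.9e-10 to 2.2e-08. They were picked among genes whose arrays of the 2 stages do not overlap, so that trait adds no evidence for them. It held for 3204 higher and 3069 lower genes of 18193, where chance gives 13.3% of genes.

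Among the other genes with the largest rises were Pou3f3, a POU-domain factor of neural progenitors (2.47 ± 0.08 SE), Neurog1, a proneural factor (2.46 ± 0.11), Zic1, a zinc finger factor of the dorsal neural tube (2.40 ± 0.06), and Rspo1, a Wnt activator of the roof plate (2.22 ± 0.09). For Rspo2, Pou3f3 and Neurog1, 1 of 2 probe sets passed the test, and for Neurod1 and Zic1 both did. The largest falls also held Ankrd1, a cardiac ankyrin repeat protein (-4.16 ± 0.10), Spink1, a trypsin inhibitor (-4.02 ± 0.12), Apoc2, a cofactor of lipoprotein lipase (-3.83 ± 0.14), and Hoxb5os, a transcript antisense to Hoxb5 (-3.77 ± 0.14).

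The neural progenitor list had 31 measured genes, of which 18 rose, 0 fell and 13 did not pass, and 20 rose and 1 fell when adjusted over the list alone. Its median log2 change was 0.36, and Fabp7, a fatty acid binding protein of radial glia, rose from 4.83 to 6.76 (1.93 ± 0.06 SE). Of 41 neuronal differentiation genes 19 rose and 3 fell, or 20 and 3 adjusted over the list alone, with a median change of 0.35. Isl1, a LIM factor of motor and sensory neurons that is also expressed in heart progenitors, was among those that fell (-1.15 ± 0.07). Of 26 Notch pathway genes 8 rose and 1 fell, or 11 and 2 adjusted over the list alone. The Notch-responsive genes Nrarp (1.24 ± 0.07) and Hes5 (1.21 ± 0.07) rose most, and Hey2 fell (-0.63 ± 0.09). Of 22 erythroid genes 8 rose and 0 fell, or 11 and 1 adjusted over the list alone, led by the embryonic globins Hba-x (1.95 ± 0.06) and Hbb-y (1.84 ± 0.06). Of 41 cell division genes 8 rose and 1 fell, or 8 and 2 adjusted over the list alone, with Mki67, a marker of cycling cells, at 0.38 ± 0.06. The shift of the cell division list was lost in limma's camera with another correlation (Benjamini-Hochberg adjusted p = 0.229 with an estimated correlation). Cardiac muscle and endoderm and yolk sac levels fell over the same interval. For the lists that rose, a changed mix of tissues cannot be told apart from a rise within cells.

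Of 28 endoderm and yolk sac genes 25 fell and 0 rose, 26 adjusted over the list alone, with a median change of -1.85. Of 22 cardiac muscle genes 19 fell and 0 rose, also 19 adjusted over the list alone, with a median of -1.81, and troponin C, Tnnc1, fell from 6.49 to 2.98 (-3.51 ± 0.09 SE). Of 33 glycolysis and hypoxia genes 22 fell and 0 rose, or 23 adjusted over the list alone, with a median of -0.38. They included Adm, the vasodilator peptide adrenomedullin (-1.78 ± 0.13), and Pfkp, a phosphofructokinase (-1.34 ± 0.12). Hox genes, which mark positions along the hindbrain and trunk, also fell, with 7 of 13 anterior and 7 of 20 posterior members lower and 0 higher, the same counts adjusted over the list alone. Hoxc8 was at least 4.69-fold lower and Hoxc4 at least 2.70-fold lower, both with GD9.0 under the background, and Hoxb1 changed by -1.51 ± 0.15. Of 24 genes of caudal progenitors and the primitive streak 9 fell and 1 rose, or 12 and 1 adjusted over the list alone. Nkx1-2, a homeobox gene of neuromesodermal progenitors (at least 6.33-fold lower, 1 of 3 probe sets), and Cyp26a1, which breaks down retinoic acid (-2.75 ± 0.14), fell most, while the Notch ligand Dll1 rose (0.51 ± 0.08). The cardiac muscle and the endoderm and yolk sac levels fell beside each of these groups.

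Further lists with a lower level at GD9.0 were surface ectoderm (10 of 26 fell, 2 rose; 11 and 2 adjusted over the list alone), with the claudin Cldn7 at -1.46 ± 0.09 SE and the keratin Krt8 at -1.29 ± 0.09. Pluripotency and epiblast genes fell in 10 of 24 cases and rose in 2, or 10 and 3 adjusted over the list alone, with L1td1 at least 2.31-fold lower, and among those that rose was Otx2, a forebrain and midbrain factor (0.52 ± 0.07). Mesoderm and mesenchyme genes moved both ways, with 14 of 38 lower and 4 higher, or 16 and 4 adjusted over the list alone. The heart and limb factor Hand2 (-3.14 ± 0.10, 1 of 3 probe sets) and Aldh1a2, a retinoic acid synthesis enzyme of paraxial mesoderm (at least 5.91-fold lower), fell. The fibrillar collagen Col3a1 (2.11 ± 0.07) and Prrx1, a mesenchymal homeobox gene (1.14 ± 0.08, 3 of 6 probe sets), rose. In the macrophage and decidua list 7 of 20 fell and 0 rose, also 7 adjusted over the list alone, and those named, Prl8a2 and Hand2, mark decidua and heart rather than macrophages. Endothelial genes (9 of 27 lower, 2 higher; 12 and 2 adjusted over the list alone) and retinoic acid pathway genes (5 of 20 lower, 3 higher; 7 and 3 adjusted over the list alone) lost their calls in limma's camera with Benjamini-Hochberg adjustment (adjusted p = 0.0829 and adjusted p = 0.136 with an estimated correlation). Sox17, a factor of endoderm and endothelium, changed by -1.73 ± 0.12, and Rbp4, the plasma retinol carrier, by -3.17 ± 0.12.

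In all, 1233 genes were higher and 1227 lower at GD9.0 than at GD8.5 by limma with Benjamini-Hochberg adjustment at 0.05, of which 106 and 188 changed at least 2-fold, and 4586 genes had an unadjusted p under 0.05. limma's camera called 17 of 38 lists, 5 higher and 12 lower, and 14 of these also with an estimated correlation. GD8.5 had 2 arrays, and without replicate 3 the counts were 774 higher and 747 lower, without replicate 4 they were 631 and 753.

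**Figure D2:**
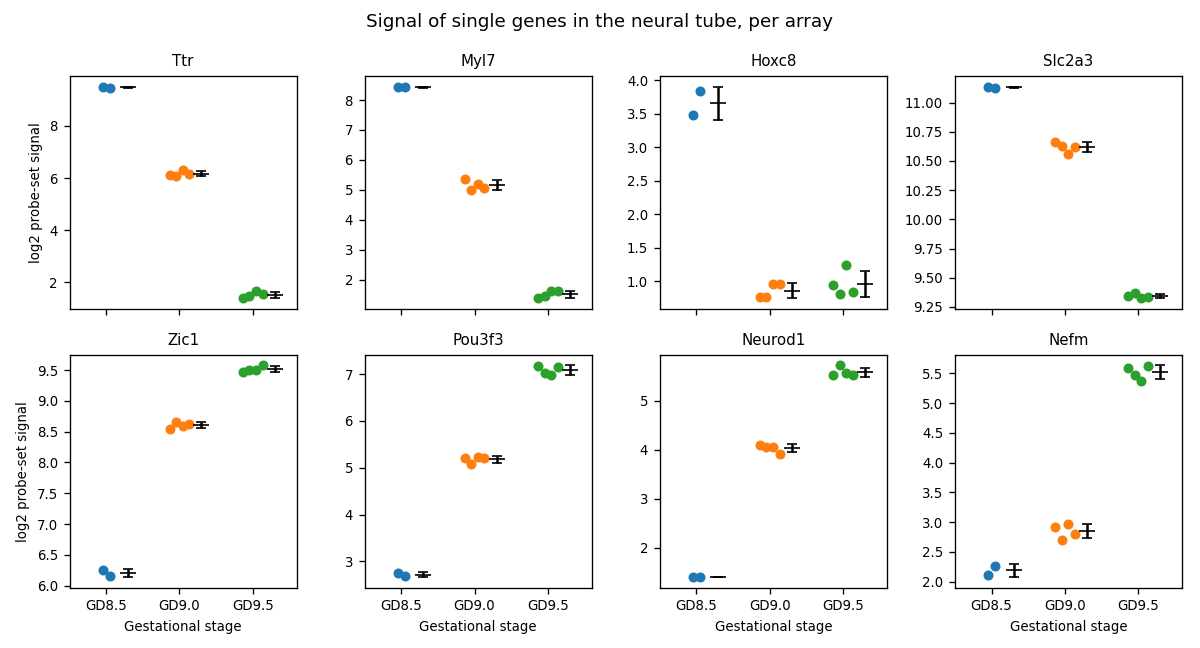
Log2 levels of 8 genes in each of the 10 log2 arrays, by stage, with points for arrays and error bars for the stage mean and SD. Ttr and Myl7 lay between 8.42 and 9.50 at GD8.5 and between 1.37 and 1.68 at GD9.5, while Zic1, Pou3f3, Neurod1 and Nefm were higher in all arrays of GD9.5 than in those of GD9.0.

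From GD9.0 to GD9.5, 29 of 41 neuronal differentiation genes rose, and 16 of 22 cardiac muscle genes and 19 of 28 endoderm and yolk sac genes fell. Nhlh2, a basic helix-loop-helix factor of young neurons, rose 9.96-fold (log2 change 3.32 ± 0.06 SE, n = 4 against 4) from 2.21 to 5.53. Nefm, the medium neurofilament subunit, rose 6.38-fold (2.67 ± 0.08). Afp, alpha-fetoprotein of the yolk sac, was 38.2-fold lower (-5.26 ± 0.09) and went from 6.79 to 1.53. Of its 5 probe sets 4 were called lower, and the 5 ranged from -5.26 to 0.10. Actc1, cardiac alpha-actin, was 18.7-fold lower (-4.22 ± 0.09), and the adjusted p of these 4 genes ranged from 4.8e-11 to 3.3e-09 by limma with Benjamini-Hochberg adjustment.

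Id4, an inhibitor of basic helix-loop-helix factors (2.97 ± 0.08 SE), Pf4, a platelet chemokine (2.82 ± 0.14), Epha3, an ephrin receptor of axon guidance (2.81 ± 0.10), and Ckb, brain creatine kinase (2.74 ± 0.06), were the other genes with the largest rises. The largest falls were in Ttr, the thyroxine carrier transthyretin (-4.64 ± 0.07), Myl7, the atrial myosin light chain (-3.64 ± 0.09), Eras, a Ras protein of embryonic stem cells (-2.74 ± 0.07), and Rbp4 (-2.57 ± 0.10). The 4 probe sets of Ttr, all called lower, ranged from -4.64 to -1.59.

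Of the 41 neuronal differentiation genes 29 rose and 0 fell, or 32 adjusted over the list alone, with a median log2 change of 0.70. Of 31 neural progenitor genes 23 rose and 2 fell, or 24 and 2 adjusted over the list alone, with a median of 0.54. Pou3f3 (1.90 ± 0.06 SE) and Gpm6a, a neuronal membrane glycoprotein (1.85 ± 0.15), rose most. Of 25 cell cycle regulators 13 rose and 1 fell, or 15 and 2 adjusted over the list alone, with a median of 0.36. Btg2, an antiproliferative gene of neurogenic divisions (1.57 ± 0.09), and Cdk6, a G1 kinase (1.43 ± 0.06), rose most. Of 26 Notch pathway genes 14 rose and 2 fell, or 16 and 3 adjusted over the list alone. Hes5 rose by 1.14 ± 0.06, while Hes1, another Notch target, changed by -0.35 ± 0.06 and the ligand Jag1 by -0.44 ± 0.06. Of 20 dorsal patterning genes 13 rose and 2 fell, or 13 and 3 adjusted over the list alone, with Zic4 (1.48 ± 0.15) and Olig3, of dorsal progenitors (1.16 ± 0.10), rising and Dlx5, of non-neural ectoderm and its border, falling (-0.56 ± 0.09). Canonical Wnt genes rose in 17 of 39 cases and fell in 5, or 18 and 5 adjusted over the list alone. Rspo3 was at 1.70 ± 0.06 (1 of 2 probe sets) and the antagonist Dkk1 at -0.96 ± 0.06 (2 of 2). Of 22 erythroid genes 10 rose and 1 fell, or 11 and 2 adjusted over the list alone, with Slc4a1, the red cell anion exchanger, at 1.44 ± 0.10. Cardiac muscle and endoderm and yolk sac levels fell in this interval too, so a changed mix of tissues may have raised these lists.

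Of 28 endoderm and yolk sac genes 19 fell and 0 rose, and of 22 cardiac muscle genes 16 fell and 0 rose, the same counts adjusted over the list alone, with medians of -0.61 and -0.45. In the glycolysis and hypoxia list 20 of 33 fell and 2 rose, or 21 and 3 adjusted over the list alone. The glucose transporters Slc2a3, from 10.6 to 9.34 (-1.27 ± 0.05 SE), and Slc2a1 (-0.72 ± 0.06) fell most, and Egln1, an oxygen sensor, rose (0.45 ± 0.07). In the surface ectoderm list 14 of 26 fell and 1 rose, or 15 and 2 adjusted over the list alone, including the simple epithelial keratin Krt18 (-1.07 ± 0.07) and its partner Krt8, from 7.10 to 6.10. Of 24 pluripotency and epiblast genes 7 fell and 0 rose, also 7 adjusted over the list alone, with Lin28a, an RNA-binding repressor of let-7 maturation, at -1.16 ± 0.08. Heart and yolk sac levels fell beside these groups, and the 18S and the actin and Gapdh 3' minus 5' measures rose. No anterior or posterior Hox gene passed, whether adjusted over all genes or adjusted over the list alone (0 of 13 and 0 of 20 by limma), with 2 and 2 at an unadjusted p under 0.05. At GD9.0, 8 of 13 anterior and 5 of 20 posterior members lay above the background, so most posterior members had no signal from which a fall could be measured, and Hoxb2 changed by -0.15 ± 0.10.

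Planar cell polarity (16 of 44 rose, 6 fell; 20 and 7 adjusted over the list alone), FGF pathway (8 of 25 rose, 1 fell; 9 and 1 adjusted over the list alone), folate and one-carbon metabolism (12 of 29 fell, 3 rose; 13 and 3 adjusted over the list alone) and endothelial genes (9 of 27 fell, 1 rose; the same adjusted over the list alone) were called by limma's camera. Their calls were lost after Benjamini-Hochberg adjustment with adjusted p = 0.213, adjusted p = 0.0713, adjusted p = 0.0713 and adjusted p = 0.202 with an estimated correlation, in that order. Gpc4, a glypican that modulates polarity signalling (0.96 ± 0.07 SE), and the atypical cadherin Celsr2 (0.87 ± 0.07) rose, as did Fgfr3, an FGF receptor (1.00 ± 0.08). For Celsr2 and Fgfr3, 1 of 2 probe sets passed the test. Gart, a purine synthesis enzyme (-0.49 ± 0.06), and Etv2, an early endothelial factor (-0.98 ± 0.11), fell.

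In all, 2561 genes were higher and 1868 lower at GD9.5 than at GD9.0 by limma with Benjamini-Hochberg adjustment at 0.05, 168 and 54 of them at least 2-fold, and 6248 had an unadjusted p under 0.05. limma's camera called 16 of 38 lists, 9 higher and 7 lower, and 12 with an estimated correlation. With all 12 arrays after log2 and quantile normalization, 1255 genes were higher and 1034 lower.

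Over the whole span from GD8.5 to GD9.5 the largest rises included neural genes and the largest falls heart and yolk sac genes. Pou3f3 was 20.7-fold higher (log2 change 4.37 ± 0.08 SE, n = 4 against 2). Nhlh2 was at least 17.2-fold and Epha3 at least 17.1-fold higher, from GD8.5 levels of 0.89 and 1.28 under the background. Ttr was 249-fold lower (-7.96 ± 0.09), from 9.48 to 1.52, and Myl7 was 121-fold lower (-6.92 ± 0.10), from 8.44 to 1.51. The 4 probe sets of Ttr, all called lower, ranged from -7.96 to -5.20. limma with Benjamini-Hochberg adjustment gave Ttr an adjusted p of 1.1e-12.

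Neurod1 (at least 17.8-fold), Cnpy1, an FGF signalling modulator of the midbrain-hindbrain border (at least 13.7-fold), and Pantr1, a noncoding RNA next to Pou3f3 (log2 change 3.79 ± 0.08 SE), were among the largest rises. Afp (-7.22 ± 0.11, 4 of 5 probe sets), Actc1 (-7.07 ± 0.11), Rbp4 (-5.74 ± 0.12) and Apoa1 (-5.65 ± 0.10) were among the largest falls. Of 41 neuronal differentiation genes 31 rose and 2 fell, or 32 and 3 adjusted over the list alone, and of 31 neural progenitor genes 26 rose and 1 fell, or 27 and 1 adjusted over the list alone. All but 2 of 28 endoderm and yolk sac genes fell (26, the same adjusted over the list alone), as did 20 of 22 cardiac muscle genes, or 21 adjusted over the list alone. In the glycolysis and hypoxia list 25 of 33 fell and 0 rose, or 25 and 1 adjusted over the list alone, with a median of -0.69. Among 13 anterior Hox genes 8 fell, or 10 adjusted over the list alone, and among 20 posterior Hox genes 9 fell, or 12, with none higher by limma in either count. Notch pathway genes rose in 14 of 26 cases and fell in 3, the same adjusted over the list alone, with Hes5 at 2.35 ± 0.07. Canonical Wnt genes rose in 14 of 39 cases and fell in 4, or 16 and 6 adjusted over the list alone. Rspo2 was at 3.70 ± 0.11 and the receptor Fzd5 at -2.14 ± 0.12, each called by 1 of 2 probe sets. Erythroid (14 of 22 rose, 2 fell; 14 and 3 adjusted over the list alone) and cell cycle regulator genes (13 of 25 rose, 3 fell; 14 and 3 adjusted over the list alone) were higher as groups. Over the whole span, too, a changed mix of tissues cannot be told apart from rises within cells.

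Lower as groups at GD9.5 were surface ectoderm (13 of 26 fell, 2 rose; 13 and 4 adjusted over the list alone), pluripotency and epiblast (11 of 24 fell, 2 rose; the same adjusted over the list alone) and endothelial genes (13 of 27 fell, 2 rose; 16 and 3 adjusted over the list alone). So were mesoderm and mesenchyme (14 of 38 fell, 5 rose; 17 and 5 adjusted over the list alone) and caudal progenitor and primitive streak genes (9 of 24 fell, 3 rose; 10 and 3 adjusted over the list alone). Dorsal patterning (11 of 20 rose, 4 fell; 11 and 6 adjusted over the list alone), macrophage and decidua (7 of 20 fell, 2 rose; 8 and 4 adjusted over the list alone) and immediate early and stress genes (9 of 27 fell, 3 rose; the same adjusted over the list alone) were called by camera with its preset correlation. After Benjamini-Hochberg adjustment in limma's camera these had adjusted p = 0.0622, adjusted p = 0.0871 and adjusted p = 0.0622 with an estimated correlation, in that order. Zic1 rose by 3.31 ± 0.06 SE, Prl8a2 changed by -3.83 ± 0.10 and the small heat shock protein Hspb1 by -1.70 ± 0.09.

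In all, 2820 genes were higher and 2389 lower at GD9.5 than at GD8.5 by limma with Benjamini-Hochberg adjustment at 0.05, 427 and 308 of them at least 2-fold, and 6805 had an unadjusted p under 0.05. limma's camera called 19 of 38 lists, 7 higher and 12 lower, and 16 with an estimated correlation. The 2 linear GD8.5 arrays were not in these fits. After log2 and quantile normalization, 184 called genes with a change of at least 2-fold and a mean level above 5 were looked at in them. In each array 100% of these genes lay on the same side of the GD9.5 mean as the GD8.5 level of the fit. This covers direction only, not the size of the change, and leaves out the dimmer genes, where the linear arrays differed more from each other.

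The change from GD9.0 to GD9.5 was compared with that from GD8.5 to GD9.0 within the fit. Prl8a2 fell in the first interval and rose in the second (1.12 ± 0.08 SE), a difference of 6.07 ± 0.16. Hoxb5os (3.74 ± 0.21) and Srgn, the proteoglycan serglycin of blood cells (3.61 ± 0.19), fell in the first interval and did not pass in the second, with GD9.5 levels of 1.72 and 1.74. Ankrd1 fell in the first, from 5.83 to 1.67, and its GD9.5 level of 1.13 lay under the background, so the fitted difference (3.63 ± 0.15) depends on that level and is 3.92 with GD9.5 raised to it. Afp fell more in the second interval (-3.29 ± 0.17), and Dmrta1, a DM-domain factor (-2.51 ± 0.24), Rnf152, a ubiquitin ligase (-2.46 ± 0.20), and Filip1, a filamin-binding protein (-2.41 ± 0.27), had their highest mean level at GD9.0. For Filip1 the change in the second interval did not pass, and 1 of its 2 probe sets was called in the first. limma with Benjamini-Hochberg adjustment gave these 8 genes adjusted p from 1.1e-08 to 0.000261.

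Relative to the first interval, the second had a higher change in 19 of 28 endoderm and yolk sac genes and a lower one in 2 (21 and 2 adjusted over the list alone), and in 13 of 22 cardiac muscle genes and a lower one in 1 (14 and 2 adjusted over the list alone), with median differences of 1.04 and 1.11. At GD9.5, 20 of 28 and 10 of 22 members lay above the background, so the floor limits the falls that the second interval could show. The difference was higher in 10 of 25 cell cycle regulators (17 adjusted over the list alone), 5 of 13 anterior Hox genes (5 adjusted over the list alone), 7 of 20 macrophage and decidua genes (10 adjusted over the list alone), 6 of 24 caudal progenitor genes (9 adjusted over the list alone) and 10 of 25 FGF pathway genes (11 adjusted over the list alone). Neuronal differentiation genes had a higher change in 15 of 41 cases and a lower one in 3, or 17 and 5 adjusted over the list alone. In limma's camera with Benjamini-Hochberg adjustment the posterior Hox, retinoic acid, neural crest, planar cell polarity, BMP and TGF-beta and cell division lists lost their calls (adjusted p = 0.0622, 0.142, 0.188, 0.238, 0.14 and 0.238 with an estimated correlation).

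The difference between the intervals passed for 1268 genes in the higher and 850 in the lower direction by limma with Benjamini-Hochberg adjustment at 0.05, 310 and 84 of them at least 2-fold on the scale of the difference. Camera called 14 of 38 lists, 8 with an estimated correlation. Without GD8.5 replicate 3 the counts were 840 and 531, without GD8.5 replicate 4 the lower count was 494, with 12 arrays they were 670 and 427, and with an intensity trend and robust spread the lower count was 1409.

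Genes called in both intervals share the GD9.0 arrays. There were 567 genes that rose in both, where independent lists would give 174, and 308 that fell in both, against 126. Another 157 rose and then fell, against 127, and 255 fell and then rose, against 173. In 100 simulations of unchanged stages on the same arrays the mean of each class was 0. No gene changed in these simulations, so they cannot show how the shared arrays affect the classes of genes that do change. With the GD9.0 arrays split between the intervals in 6 ways, 383 to 484 genes rose in both, 206 to 250 fell in both, 54 to 82 rose and then fell, and 122 to 148 fell and then rose.

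Over the 3 stages 5982 genes changed by limma's F test with Benjamini-Hochberg adjustment at 0.05, 776 of them with a change of at least 2-fold. A gene was called constitutive when the 95% intervals of all stage differences lay within 0.5 on the log2 scale and its mean level was above the 75th percentile, and 3314 genes met this, 72.9% of those above that level. The genes with the highest levels among them were Rpl41, Rps29 and Rps2 of the ribosome, Eef1a1, a translation elongation factor, Tpt1, a translationally controlled tumour protein, and Tmsb10, an actin-binding thymosin. Eef1a1 stood at 12.29 ± 0.02 (SD, n = 2), 12.35 ± 0.03 (n = 4) and 12.31 ± 0.03 (n = 4), and Rps2 at 12.05 ± 0.01, 12.08 ± 0.06 and 11.96 ± 0.03. These levels lay near the array maxima, which ranged from 12.6 to 12.8. Whether the top of the scale limits the change such genes can show was not tested. With the interval set to 0.3, 1463 genes met the rule. The rule did not leave out genes that the F test called, so genes with small changes may be in both counts. How many are in both was not counted.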

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

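The tests of the heart, yolk sac and Hox patterns, and the count of splits for lists with an estimated correlation, were chosen after the results had been seen, while those of the glycolysis and hypoxia pattern and the other split counts were written before.

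Heart and yolk sac genes were highest at GD8.5 and lowest at GD9.5. Genes matched on level had a median log2 change from GD8.5 to GD9.5 of -0.017 (95% bootstrap interval -0.035 to -0.00076). No shift shared by genes of that level was thus left in the values. The arrays had nearly the same distribution before this test, which holds such a median near 0. It therefore cannot decide whether a difference in normalization was involved. Heart and yolk sac tissue carried over into the earlier dissections may be a reason, and the labels give no dissection margins that would exclude it. That 100% of the members more than 1 log2 unit above background at GD8.5 fell (16 of 16 cardiac, 22 of 22 endoderm and yolk sac) restates the pattern on genes picked for a high level at GD8.5 and decides nothing, so this stays open. Ttr stood at 9.48 and Actc1 at 9.24 at GD8.5, 8 of the 16 and 18 of the 22 were still above background at GD9.5, and a change with stage within neural cells stays open and untested.

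Hox genes were lower at GD9.0 and GD9.5 than at GD8.5, and 7 of the 8 well above background at GD8.5 fell. These 8, and the genes counted below, were picked for a high level at GD8.5, which favours falls. Picked in the same way, 7 of 24 brain regional identity genes fell and 10 rose. Less caudal neural tissue in the later dissections may be the reason, and 50% of the well-expressed caudal progenitor and primitive streak genes fell (6 of 12, with 2 higher), which neither bears it out nor excludes it. Trunk mesoderm carried over into the GD8.5 dissections cannot be told apart either, since 57.1% of the well-expressed mesoderm genes fell (12 of 21, with 4 higher). Lower expression in the cells themselves also stays open and was not tested.

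Glycolysis and hypoxia genes were lower at GD9.5 than at GD9.0. With the cardiac and yolk sac levels in the fit the mean change of the list was -0.038 (95% interval -1.89 to 1.82), against -0.25 (-0.29 to -0.20) without them, and because those levels nearly repeat the stages the loss of such tissue cannot be told apart from stage. A lower hypoxia response might also be involved. The hypoxia-induced members had a median change of -0.21 (95% bootstrap interval -0.28 to -0.017), against -0.30 for the enzymes and transporters. The interval lay below 0, but the median did not reach the -0.30 set beforehand for a lower response, so this stays undecided. The bootstrap resampled genes, not arrays, so its interval does not measure the spread between arrays.

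For GD9.5 against GD9.0, the gene count was compared with that of other groupings of the 8 arrays. Of 35 splits into 4 and 4, 1 gave as many genes as the real split, the real split itself. It gave 4429 genes by limma, against a highest other of 0. A share of 1 of 35 is the smallest that these splits can give, so chance is made unlikely but not excluded. Every other split has arrays of both stages on each side, which adds the stage difference to its spread. Gaps between the real and the other splits therefore do not measure the strength of a difference. For lists called by camera with its preset correlation 1 of 35 splits gave 16, but another split gave 15, so single list calls at the preset correlation carry little weight. With an estimated correlation the real split gave 12 lists and the highest other 0, again 1 of 35 splits. The GD8.5 comparisons have 2 arrays on 1 side and were not counted in this way.

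For 15 of 304 tested groups of 4 arrays (4.93%), over lists and the genes named in the text, 1 array lay far from the other 3, where chance gives about 1 in 20. The list mean of chromatin and DNA methylation genes in GD9.0 replicate 3 was 5.68 against 5.64 in the other 3 arrays, that of extracellular matrix and adhesion genes in the same array 4.68 against 4.65, and that of folate and one-carbon genes in GD9.5 replicate 3 5.25 against 5.22. In GD9.0, Cnpy1 stood at 2.92 in replicate 4 (other arrays 3.38), Dmrta1 at 4.34 (4.72) and Prl8a2 at 4.27 (4.60) in replicate 1, and Nhlh2 at 2.11 (2.25), Olig3 at 1.66 (1.88) and Pou3f3 at 5.08 (5.22) in replicate 2. In GD9.5, Hand2 stood at 1.38 (1.26) in replicate 3, Lrp2 at 4.18 (4.34) and Slc2a1 at 9.43 (9.62) in replicate 2, Xist at 9.24 (9.13) in replicate 2, Eif2s3y at 4.66 (4.48) in replicate 4, and Mki67 at 9.24 (9.20) in replicate 1. Outside the gene measurements, the 18S control probe sets were higher at GD9.5 than at GD9.0 by 1.47. Gene changes that differed between the intervals by limma's test of the difference, as the second minus the first, were 6.07 for Prl8a2, 3.74 for Hoxb5os, 3.63 for Ankrd1 (3.92 with its GD9.5 level, which lay under the background, raised to it), 3.61 for Srgn, -3.29 for Afp, -2.51 for Dmrta1, -2.46 for Rnf152 and -2.41 for Filip1. Lists whose median differed were cardiac muscle (1.11), endoderm and yolk sac (1.04), anterior Hox (0.40), cell cycle regulators (0.38), macrophage and decidua (0.36), neuronal differentiation (0.30), caudal progenitor and primitive streak (0.30) and FGF pathway (0.28).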

How the results depend on the processing

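The fits of 12 arrays, those with tissue levels and the list medians with stage means raised to the background were chosen after seeing the data. A turn in direction was counted only where the main fit or the alternative made a call, and sign changes without a call counted as kept. Counted in this way, scaling and filter alternatives turned no list in direction. Apart from the 2-fold threshold, fry and the tissue levels, 331 of 387 named gene values had a value in every fit, and 268 of these kept direction and call throughout. The other 56 had no value in at least 1 fit with fewer probe sets, and 48 of these kept both where fitted. Of 152 list shifts 144 had a value in every fit, and 103 of these kept both, as did 6 of the other 8 where fitted. With stage means raised to the background 16 list medians moved by more than their spread between arrays, and no called list turned in sign. Among them the difference between the intervals went to 0.22 for neuronal differentiation, 0.28 for macrophage and decidua and 0 for posterior Hox. The values that turned with a call in either fit were the following. Smad2, GD9.5 against GD9.0, was at -0.19 with the mean of probe sets. Coro1a was at -0.12 (GD9.5 against GD9.0) and -0.026 (GD9.5 against GD8.5) without shared probe sets. The extracellular matrix list (GD9.5 against GD8.5), with a median of -0.064, was not called and lower by camera but higher by fry. Other lists, called by neither camera nor fry, also had opposite directions, among them cell cycle regulators for GD9.0 against GD8.5. The cause was not tested.

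Counts moved over 1.5 times as follows. The 2-fold threshold left 106 and 188, 168 and 54, 427 and 308, and 310 and 84 genes, and 776 by the F test, as fewer genes can pass it. The 0.3 interval left 1463 constitutive genes. The intensity trend gave 1409 lower differences, and 12 arrays gave 1255 and 1034 genes for GD9.5 against GD9.0 and 670 and 427 differences; the cause was not tested. Of 4429 genes called for GD9.5 against GD9.0, 2274 were also called in the same direction with 12 arrays, of 2460 for GD9.0 against GD8.5 1765, of 5209 for GD9.5 against GD8.5 3916 and of 2118 differences 1065. fry called 30, 30, 31 and 29 lists, and camera with an estimated correlation 8 for the difference.

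With the cardiac and yolk sac levels as covariates 0 genes and 0 lists were called by limma in each contrast, with 772, 802, 783 and 771 genes at an unadjusted p under 0.05, 988 genes by the F test and 0 were constitutive. Stage held 99.85% and 99.98% of the variance of these levels, and median standard errors were 57.0, 32.8 and 83.8 times larger, so this fit cannot separate them from stage. In it 28 of 152 list shifts and 153 of 387 named gene values had a call in the main fit and changed sign. These are not listed singly, and sign changes of values without a call were not counted.

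Leaving out each of 10 arrays gave 631 to 1199 higher and 747 to 1205 lower genes for GD9.0 against GD8.5, the lowest without GD8.5 replicate 4 and replicate 3. The other ranges were 2110 to 2487 and 1561 to 1785 for GD9.5 against GD9.0, 1951 to 2804 and 1624 to 2390 for GD9.5 against GD8.5, 840 to 1198 and 494 to 743 for the difference, 4867 to 5690 by the F test and 2961 to 3295 constitutive. Lists called ranged over 16 to 18, 14 to 18, 19 to 19 and 12 to 15. Equal replicate numbers did not pair the arrays (correlations of deviations for GD9.0 and GD9.5 -0.027, 0.122, 0.0614 and 0.0328), and a replicate block gave 981 and 918, 2402 and 1774, and 2574 and 2054 genes. Median centring moved the share of higher calls for GD9.5 against GD9.0 from 57.8% to 65.3%. Signal near the background limits dim genes, and 13018 of 18193 genes lay above it; no value was possible for the posterior Hox list over the brighter genes, nor for it and the sex chromosome list with the brighter probe sets.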

Other observations

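The tests in this part were fixed before the data were examined, apart from the choice of which lists to describe. Genes of the microRNA and let-7 pathways moved both ways. Lin28a, which blocks let-7 maturation, went from 7.77 at GD8.5 to 7.08 and 5.93 (log2 change -1.84 ± 0.09 SE from GD8.5 to GD9.5, n = 4 against 2). Ago1, an Argonaute protein, rose by 1.21 ± 0.08. In the microRNA pathway list 4 of 25 genes rose and 3 fell from GD8.5 to GD9.5, or 5 and 4 adjusted over the list alone, and in the let-7 target list 7 of 23 rose and 5 fell, the same adjusted over the list alone. Among let-7 targets Nr6a1, a nuclear receptor of the early embryo, fell by 2.02 and Plagl1, an imprinted zinc finger gene, rose by 1.66. Neither list was called (limma camera, Benjamini-Hochberg adjusted p = 0.89 and 0.98). Dnmt3b, a de novo DNA methyltransferase, went from 8.54 to 7.63 and 6.94, while the chromatin list as a whole had 6 of 36 genes higher and 7 lower, or 7 and 7 adjusted over the list alone.

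Regional and closure genes also moved apart within their lists from GD8.5 to GD9.5. Of 33 brain regional identity genes 12 rose and 9 fell, or 14 and 10 adjusted over the list alone. Wnt8b, of the dorsal forebrain, rose by 2.55 ± 0.07 SE and Dmrta2, a forebrain factor, by 2.37 ± 0.07, whereas Hesx1, of the anterior neural plate, changed by -3.73 ± 0.07 and Egr2, of hindbrain rhombomeres, was at least 6.87-fold lower, with GD9.5 under the background. Of 58 neural tube closure genes 14 rose and 14 fell, or 15 and 16 adjusted over the list alone, with Zic5 at 1.29 ± 0.07 and Lrp2, an endocytic receptor, at -1.02 ± 0.11. In the Sonic hedgehog and ventral patterning list 9 of 25 rose and 5 fell, the same adjusted over the list alone. Dbx1, of intermediate progenitors, was at 3.20 ± 0.10 and Foxa2, of floor plate and notochord, at -1.45 ± 0.09. Foxa2 is also in the endoderm and yolk sac list, of which 26 of 28 genes fell. In the axon guidance list 16 of 44 rose and 9 fell, or 17 and 14 adjusted over the list alone. Of 35 oxidative phosphorylation genes 8 rose and 1 fell, also 8 and 1 adjusted over the list alone, with a median of 0.049. None of these 5 lists, nor the chromatin list, was called by limma's camera (adjusted p from 0.0869 to 0.981).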
